A study of Homo sapiens with 3 samples.

How the data were processed

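Gene expression was measured in HEK293T cells, a human embryonic kidney cell line that carries the SV40 large T antigen, on 3 single-channel arrays. Per the labels' protocols, the cells were transfected in 6-well plates with Fugene HD, and total RNA was extracted with a column kit. All 3 samples received dCas9VP160, a nuclease-dead Cas9 joined to the VP160 activation domain, and differed in the guide RNA. The deposited table holds log2 values for 22277 probe sets with Affymetrix identifiers, with 1 column per array and no missing value. The log2 unit was taken from the values: they ran from 1.36 to 14.5, which lies within the range of a 16-bit scanner on a log2 scale and beyond it on a natural log scale. The authors used the affy package, per the submitters' processing notes, which give neither its version nor the background correction, normalization or summary method. These are not given in the sources used here. The sorted values of the 3 deposited columns lay within 0.104 log2 units of their common mean at every rank, so the arrays had been brought to nearly the same distribution. Such scaling removes a shift shared by all genes, and a difference is therefore relative to the bulk of genes. Between 6.21% and 8.25% of probe sets held exactly the same value on a given pair of arrays. The labels name the dye as Cy3.

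Probe sets were named from GEO's annotation of the array. Of the 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and were not named, and 2164 were not listed there and stayed unnamed, among them 62 chip controls. The gene identifiers of 19058 of the 19070 sets were found in the GRCh38.p14 gene table, and no symbol needed an update. The 19070 sets gave 11963 genes, 4310 of them with more than 1 set, and the set with the highest mean over the 3 arrays stood for its gene. No detection calls were used. The 27 probe sets for Bacillus subtilis transcripts on the chip were taken as a background scale after the data were seen, and a gene at or under the highest of them on an array was treated as not above background there. That highest value was 3.29 on the sgTetOmut array and 3.40 on the other two. Between 76.0% and 77.8% of genes lay above it. A fold over such a gene is given as "at least", computed against the highest Bacillus value.

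Each group held 1 array, so no test between conditions was possible, no p-value is given, and no difference has a replicate check. The number of arrays limits the precision. The following choices were made before the data were examined. A gene was counted when its value on one array lay at least 1 log2 unit (2-fold) above, or below, both other arrays. The rule was applied to each of the 3 arrays, so the control arrays give its background. Pairs of arrays were counted with the same size limit. In each case the higher of the values compared had to reach the median of all named genes on its array, 6.19 on sgTetOmut and sgTetO and 6.23 on sgIL1RN1~3. The named genes were IL1RN, the 10 genes furthest above and the 10 furthest below both control arrays on sgIL1RN1~3, the 10 highest and 10 lowest differences between sgTetO and sgTetOmut, up to 3 members of each gene list with the largest difference of sgIL1RN1~3 from the mean of both controls, and all measured members of the IL-1 cluster list. The 20 genes furthest above both other arrays on sgTetOmut were added after the data were seen. The 20 gene lists, 461 entries of which 391 were measured, covered the IL-1 cluster and its neighbours, IL-1 receptor signalling, the NF-kB response, the interferon response, heat shock, the unfolded protein and amino acid response, p53 targets, immediate early genes, mitosis, DNA replication, cholesterol synthesis, hypoxia and glycolysis, histones, ribosomal proteins, oxidative phosphorylation, pluripotency genes, and markers of blood and endothelial cells, of fibroblasts and muscle, of epithelia and liver, and of neurons and adrenal cells. Older symbols were matched through synonyms. For each list the median log2 difference was set against 10000 random lists of the same size, drawn for each member from the 100 genes nearest in mean level. The resulting percentile describes these arrays and is no test of the guides.

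Alternatives were quantile and cyclic loess scaling (limma 3.58.1 in R 4.3.3), other minimum levels, the mean of all probe sets of a gene, 16 added to the linear values, limits of 1.5-fold and 3-fold, and single control arrays as reference. Other computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The counting rule was tested on simulated data in which 200 of 11963 genes were raised on the sgIL1RN1~3 array, with noise drawn from the 2 control arrays. It recovered 100% of the 50 genes raised 3-fold, 100% of those raised 4-fold and 100% of those raised 8-fold, 32% of those raised exactly 2-fold, and made 2 false calls. A simulated list of 25 genes shifted by 0.3 log2 units lay at percentile 100 of the random lists. The raised and shifted genes were drawn from those whose control mean reached the median level. Genes at background on the controls, such as IL1RN, were thus not simulated. At or above the median level, the scaled median absolute deviation of differences was 0.12 between the controls. It was 0.19 and 0.21 for sgIL1RN1~3 against sgTetOmut and sgTetO, so the simulated noise was the smaller.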

Results

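The study used a CRISPR-based transcriptional activator in HEK293T cells and asked how gene expression changed with the guide RNA that directed it. The 3 arrays were 1 with sgTetOmut, a mutated guide with no target that served as control, 1 with sgTetO, directed to the TetO promoter, and 1 with sgIL1RN1~3, directed to the promoter of IL1RN. TetO is a bacterial operator sequence used in inducible transgenes, and the labels give sgTetO no human target. Each guide was measured on 1 array, so the values below carry no replicate error, and the second control array is the available measure of how far arrays differ. Across 11963 named genes the arrays were close: Pearson's r was 0.997 between sgTetO and sgTetOmut, 0.996 between sgIL1RN1~3 and sgTetO and 0.996 between sgIL1RN1~3 and sgTetOmut, with genes not being independent replicates. Among genes at or above the median level, 98.7% differed by under 0.5 log2 units between the 2 control arrays, against 94.0% between sgIL1RN1~3 and sgTetO and 95.6% between sgIL1RN1~3 and sgTetOmut.

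The first comparison asks whether the gene targeted by the guides was higher on its own array. IL1RN, which encodes the interleukin-1 receptor antagonist, a secreted protein that blocks the IL-1 receptor, had a log2 value of 7.01 with sgIL1RN1~3, 2.28 with sgTetO and 2.23 with sgTetOmut. These values differ by 4.73 log2 units from sgTetO and 4.78 from sgTetOmut, the highest of 11963 genes in both cases. Both control values of this probe set lay within the range of the Bacillus probe sets, so it was not above background there, and its fold is bounded as at least 12.2-fold over sgTetO and at least 13.2-fold over sgTetOmut. The 2 controls differed by 0.06 at IL1RN, and by an SD of 0.25 over the 100 genes nearest to it in mean level over the 3 arrays. That mean, 3.84, lies between the control values of IL1RN and its value with sgIL1RN1~3. The SD therefore describes genes near the highest Bacillus values and gives no spread for the difference of 4.73.

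The large difference came from 1 of the 5 IL1RN probe sets, 212657_s_at. This set had the highest mean over the 3 arrays only through its value on sgIL1RN1~3. On both control arrays 212659_s_at was brighter. The rank of IL1RN and its place past the 2-fold limit thus rest on a set chosen partly by the array compared. The second set, 212659_s_at, read 3.80 with sgIL1RN1~3 against 2.88 with sgTetO and 3.29 with sgTetOmut. It differed by 0.93 and 0.52 log2 units, under the limit. The difference from sgTetOmut was 1.43-fold, and on sgTetOmut it lay at the highest Bacillus value and barely above it. The other 3 sets, 216243_s_at, 216244_at and 216245_at, were at background on all 3 arrays, sgIL1RN1~3 included. With the mean of all 5 sets, and thus of these 3, the difference was 0.94 over sgTetO and 0.89 over sgTetOmut, and IL1RN then ranked 15 and 18 among all genes.

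**Figure D1:**
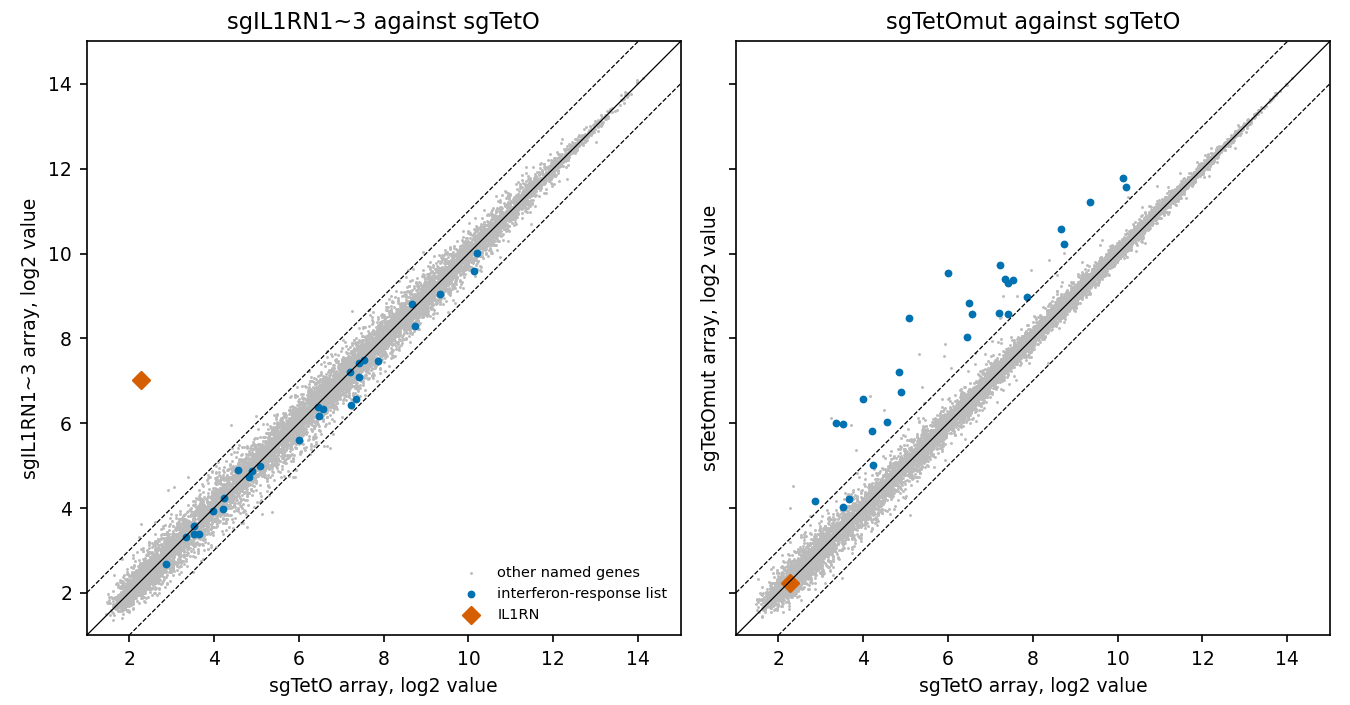
Log2 values of 11963 named genes (1 point per gene, 1 array per guide), with sgTetO on the horizontal axis and sgIL1RN1~3 (left) or sgTetOmut (right) on the vertical axis; the solid line marks equality and the dashed lines a difference of 1 log2 unit. IL1RN (diamond) stands 4.73 above the line on the left, and the 28 measured genes of the interferon-response list (dark circles) lie above the line on the right.

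The second comparison asks which other genes differed with the IL1RN guides. IL1RN, by set 212657_s_at, was the 1 gene at least 2-fold above both controls on sgIL1RN1~3. MICOS10P1, annotated as a pseudogene, was the 1 gene at least 2-fold below both (5.41 against 6.74 with sgTetO and 6.60 with sgTetOmut). By the same rule sgTetO had 0 genes above and 0 below both other arrays, while sgTetOmut had 35 above and 0 below. Among genes at or above the median level, those next furthest above both controls on sgIL1RN1~3 were PPP2R1A, a scaffold subunit of a protein phosphatase, by at least 0.91 log2 units, ATP6V0D1, a subunit of the vacuolar proton pump, by at least 0.87, TENT5C, a poly(A) polymerase, by at least 0.80, and VCP, an ATPase of protein degradation, by at least 0.79. KAT6A, a histone acetyltransferase, ANXA6, RHOC, GPC3 and AP2A2 followed with 0.77 to 0.74. The second VCP set did not show this, at 7.56 with sgIL1RN1~3 against 7.54 and 7.55 on the controls, and the second KAT6A set was at background on all 3 arrays. Genes under the median level that lay further apart, such as FGFBP1 by 1.53, are given in the closing observations.

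Below both controls on sgIL1RN1~3 after MICOS10P1, at or above the same level, were CYP3A5, a drug-metabolising cytochrome, by at least 0.90 log2 units, KIF13A, a kinesin, by 0.86, SLC6A16, of a transporter family, by 0.83, and ABCA5, ATAD5, NSMAF and DKFZP586I1420 by 0.79 to 0.78. The other 2 CYP3A5 sets were at or within 0.06 of the highest Bacillus value on sgIL1RN1~3, and hybridization of transcripts of its close relatives cannot be excluded here. IFI44 and IFIH1, the second of them a sensor of double-stranded RNA, were also below both controls, by 0.79 and 0.77 relative to sgTetO and by 3.28 and 2.81 relative to sgTetOmut. With sgTetO as the only control, chosen after seeing the data, 6 genes were at least 2-fold higher (IL1RN, KAT6A, KPNA6, PPP2R1A, RNF19B and SLC29A1) and 4 were lower (KIF13A, MICOS10P1, SLC6A16 and ZNF814). Under quantile and cyclic loess scaling PPP2R1A and RNF19B fell short of the limit, leaving 4 higher genes, and NANOG passed it, making 5 lower. Of the further KPNA6 sets, one was 0.65 higher than on sgTetO and one 0.12 lower, and that of SLC29A1 was 0.27 higher. At a limit of 1.5-fold, 40 genes were above and 35 below both controls on sgIL1RN1~3, against 1 and 1 on sgTetO and 44 and 1 on sgTetOmut.

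The sgIL1RN1~3 array also differed from both controls in its chip controls for the transcripts of ACTB (beta-actin) and GAPDH, which measure RNA integrity and how far labelling reached. The 5' set of ACTB was 0.82 and 0.95 log2 units higher than on sgTetOmut and sgTetO, while its 3' set was 0.07 and 0.06 higher. The 5' set of GAPDH was 0.66 and 0.84 higher, and its 3' set differed by 0.03 and -0.01. Between the 2 controls the 5' sets differed by -0.13 for ACTB and -0.18 for GAPDH. These differences are of the size of those of the genes named after IL1RN and moved with the same array.

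**Figure D2:**
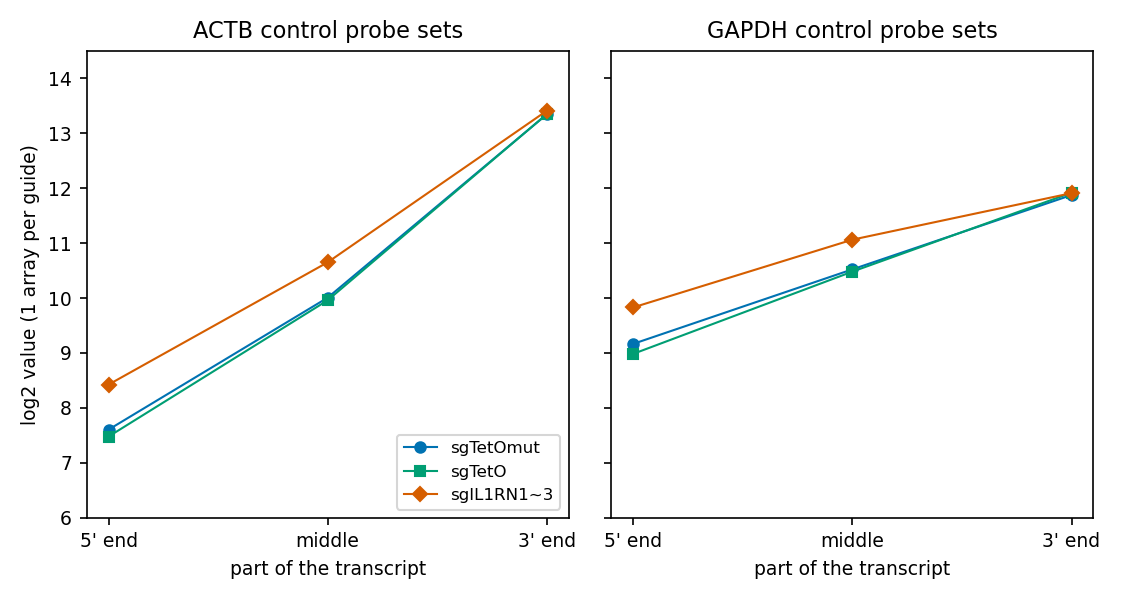
Log2 values of the 5', middle and 3' control probe sets of ACTB and GAPDH on the 3 arrays, with 1 point per array and part of the transcript. The sgIL1RN1~3 array lies 0.66 to 0.95 above the controls at the 5' end and within 0.07 of them at the 3' end.

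The third comparison sets the control guides against each other. Genes of the interferon response were higher on sgTetOmut than on sgTetO and on sgIL1RN1~3: all 28 measured members of the list were highest on sgTetOmut, and 25 were at least 2-fold above both other arrays, or 24 when bounded by background. The 20 members at or above the median level, which some reached through sgTetOmut alone, were among them. The list's median was 1.85 log2 units (3.61-fold) above the mean of the other arrays. RSAD2, an antiviral enzyme, was 3.55 log2 units lower with sgTetO than with sgTetOmut. OAS2, OASL, OAS1 and OAS3, which bind double-stranded RNA, were 3.40, 2.38, 2.34 and 2.00 lower. IFIT3 was 2.58 lower, IFI44 was 2.49 lower and IFIH1 was 2.04 lower. PSMB9, a subunit of the immunoproteasome, and SP100, a nuclear body protein, both outside the fixed list, were 2.47 and 2.30 lower.

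These differences were of like size for sgIL1RN1~3, where RSAD2 was 3.94 and OAS2 3.50 lower than with sgTetOmut. The abundant members ISG15, a ubiquitin-like protein, IFITM1, which restricts virus entry, and IFIT1 had log2 values of 9.37, 11.2 and 11.8 with sgTetOmut, and were lower by 1.84, 1.88 and 1.67 with sgTetO. IFI6 and IFI27 were lower by 1.90 and 1.84. Of the 35 genes at least 2-fold above both other arrays on sgTetOmut, 20 were on the fixed interferon list. The other 15 included SP110, TRIM22, UBE2L6, SHFL, DDX60, IFI35 and TAP1. Of the 14 further probe sets of these 35 genes, 13 were also highest on sgTetOmut and 7 by at least 2-fold. IFITM1 and IFITM3 are near-identical paralogs, and their probe sets can share transcripts.

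**Figure D3:**
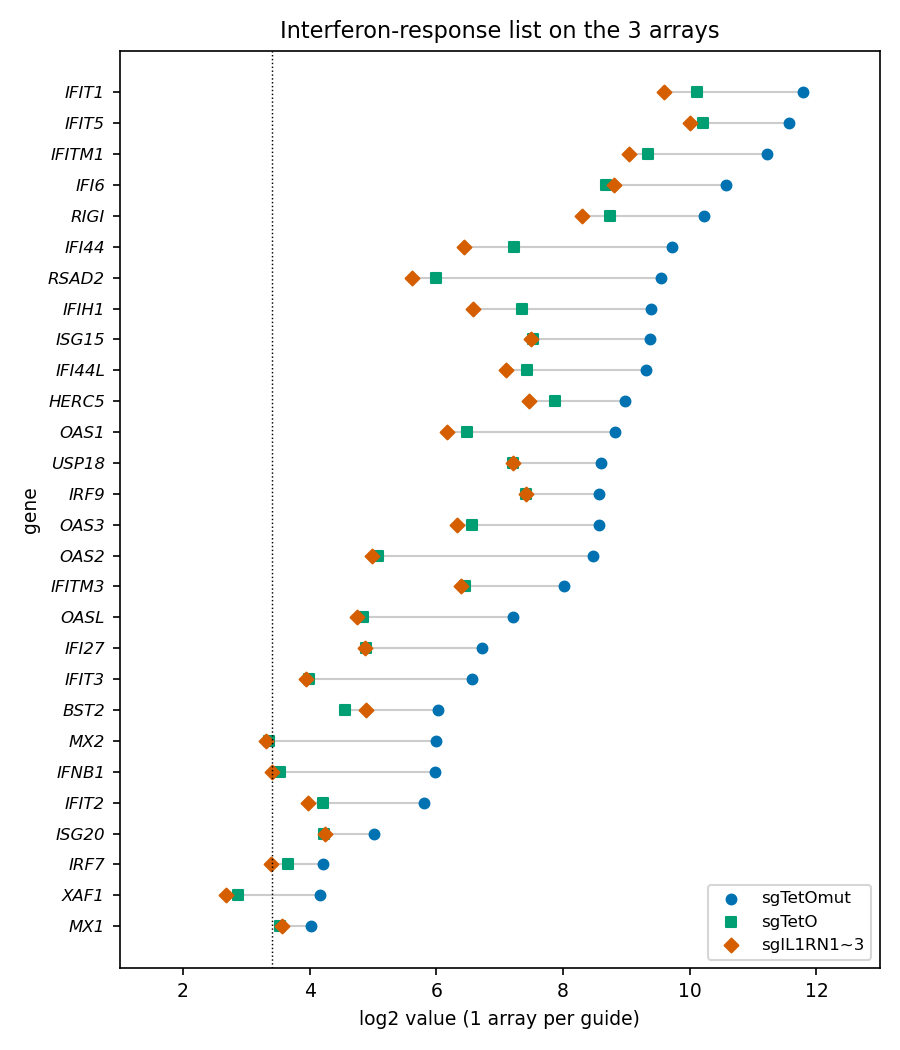
Log2 values of the 28 measured genes of the interferon-response list (rows) on the 3 arrays, with 1 point per array and the dotted line at 3.40, the highest Bacillus control value. sgTetOmut (circles) is highest for all 28 genes.

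Compared in pairs, 37 genes were at least 2-fold lower with sgTetO than with sgTetOmut, 20 of them on the interferon list and 17 outside it, and 0 were higher. Among genes at or above the median level, those furthest up with sgTetO were CRCP, a receptor component and polymerase subunit, by 0.93 log2 units, TRMT2B, a tRNA methyltransferase, by 0.77, AASS, a lysine-degrading enzyme, by 0.66, and LPL, lipoprotein lipase, by 0.60. ANKRD11, NOVA1, TTC9, SSTR2, ZNF79 and TPH1 followed with 0.57 to 0.51. Further sets of these genes differed: by 0.14 for CRCP, 0.10 for AASS, 0.11 for NOVA1, 0.42 for one ZNF79 set and -0.26 for TTC9, while those of LPL and SSTR2 and another of ZNF79 were at background on sgTetO. Against sgTetOmut, sgIL1RN1~3 had 38 genes at least 2-fold lower, 20 of them on the interferon list, and 2 higher, IL1RN and ERBB2.

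Among the other IL-1 genes no activation of 2-fold was seen. Of the 11 measured members of the IL-1 cluster list, IL1RN alone passed the limit. IL1B, IL37, IL36A, IL36G, IL36RN and PSD4 were at background on all 3 arrays. IL1A differed from the controls by -0.17 and -0.05, PAX8 by -0.17 and 0.00, POLR1B by 0.00 and 0.12, and SLC20A1, a phosphate transporter, by -0.26 and -0.26. The list's median difference from the mean of both controls was -0.05 (percentile 17.5 of random lists), and its mean, 0.40, had the opposite sign because of IL1RN. The 18 measured genes of IL-1 receptor signalling had a median of -0.02 (percentile 24.3). IRAK1 was 0.40 and 0.31, IL1RAP 0.16 and 0.30, and MAP3K7 -0.09 and -0.08 away from sgTetO and sgTetOmut. The second IL1RAP set read -0.06 against each control, and further MAP3K7 sets read 0.21, -0.23 and -0.05 against sgTetO. The 21 measured NF-kB response genes had a median of -0.00 (percentile 20.8) and a mean of 0.01, with IER3 0.53 and 0.13, NFKBIA 0.42 and 0.19, and TNFAIP3 -0.10 and -0.19 away from sgTetO and sgTetOmut.

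By the probe sets that stand for the genes, the remaining lists held 0 genes 2-fold apart from both controls on sgIL1RN1~3. The interferon list had a median of -1.11 against the mean of both controls, -1.91 against sgTetOmut alone and -0.16 against sgTetO alone. Besides it, 3 of the 20 lists lay outside the central 95% of matched random lists against the mean of both controls, and each lay inside it against one of the controls alone. The 22 measured genes of hypoxia and glycolysis had a median of 0.08 (percentile 98.0), and 0.06 against sgTetOmut alone (percentile 96.6). ENO1 was 0.52 and 0.49, SLC2A3 0.55 and 0.23, and NDRG1 0.44 and 0.22 above sgTetO and sgTetOmut. Further ENO1 sets were 1.29 and 1.21, past the 2-fold limit on both, and 1.05 and 0.89 above them. Further SLC2A3 sets differed by 0.34 and 0.19, and by 0.01 and -0.19. The 20 ribosomal protein genes had a median of 0.04 (percentile 99.1), and 0.02 against sgTetOmut alone (percentile 91.7), with RPL8, RPL18 and RPS3 0.43, 0.38 and 0.31 above sgTetO, though 2 further RPL18 sets were 0.11 and 0.33 lower. The 25 genes of oxidative phosphorylation had a median of -0.09 (percentile 0.295), -0.02 against sgTetO alone (percentile 11.5), but a mean of 0.03, and its members furthest from the controls, UQCRC1, NDUFV1 and SDHA, were higher by 0.69, 0.63 and 0.50 than on sgTetO. Under quantile scaling the hypoxia list (percentile 95.6) and the ribosomal list (percentile 97.4) lay inside the random range, and under cyclic loess the hypoxia list did (percentile 97.2). Against the mean of both controls these shifts were under 0.1 log2 units. The ribosomal and oxidative phosphorylation lists also differed between the controls, with medians of -0.08 each for sgTetO minus sgTetOmut (percentiles 0.03 and 1.63). Their shifts can therefore not be assigned to the sgIL1RN1~3 array. The hypoxia list lay inside the random range between the controls (-0.04, percentile 28.1). Its shift moved with the array whose 5' control sets were 0.66 to 0.95 higher.

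Stress and growth lists lay within the random range on sgIL1RN1~3 against the mean of both controls. The 15 measured p53 targets had a median of 0.12 (percentile 97.2), but lay above the range against sgTetOmut alone (0.15, percentile 99.2) and under cyclic loess scaling (0.11, percentile 97.8), with BAX, CDKN1A and FAS 0.48, 0.53 and 0.31 above sgTetO, though further FAS sets read 0.44, 0.01 and -0.12. The unfolded protein and amino acid response had 0.09 (percentile 95), with DDIT4 and ATF3 each 0.67 and PSAT1 0.47 above sgTetO. Immediate early genes had 0.08 (percentile 93.8), with MYC at 0.58, JUN at 0.61 and DUSP5 at 0.43 relative to sgTetO, as for the genes that follow. Further JUN sets read 0.47, 0.16 and 0.13. Heat shock genes had -0.06 (percentile 4.79), with DNAJB1, HSPB1 and DNAJB4 at 0.26, 0.31 and -0.19. The second DNAJB1 set read -0.10. Mitosis genes had 0.02 (percentile 79.5) and a mean of -0.01, with PLK1 at 0.57 and TTK and KIF23 at -0.46 and -0.51. DNA replication genes had 0.02 (percentile 64.8), with MCM7, CDT1 and CDC6 at 0.68, 0.56 and -0.45. Further sets of MCM7 and CDC6 read 0.97 and -0.17. Cholesterol genes had -0.03 (percentile 20.7), with SQLE, FDPS and NSDHL at -0.35, 0.36 and -0.29, while further sets of SQLE and NSDHL above background read 0.52 and 0.46, and another SQLE set 0.02. Histone genes, whose copies are near-identical, had 0.01 (percentile 54.3), with H2BC21, H2AC6 and H2BC5 at 0.83, 0.22 and 0.00. Pluripotency genes had 0.03 (percentile 56.7), with NANOG, which has several pseudogenes, at -0.99 and DNMT3B at -0.05.

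Markers of other cell types lay within the random range. On sgIL1RN1~3 the median was 0.08 for blood and endothelial cells (percentile 86.7), 0.06 for fibroblasts and muscle (percentile 76.8, mean -0.00), with ACTA2, COL1A1 and COL3A1 0.13, 0.16 and 0.10 above sgTetO, -0.02 for epithelia and liver (percentile 27.9, mean 0.01), with SFN at 0.83 and KRT10 at -0.06, and -0.01 for neurons and adrenal cells (percentile 28.0), with NEFL, TUBB3 and GAP43 at 0.26, 0.17 and 0.28. Further NEFL sets read 0.32 and -0.09 against sgTetO. None of the blood and endothelial markers reached the median level on any array. The 4, 2 and 5 members of the other lists that did were under 2-fold apart from both other arrays on each of the 3 arrays.

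Between the 2 controls the interferon list had a median of -1.84 for sgTetO minus sgTetOmut, and 3 other lists lay below the central 95% of random lists. These were the NF-kB response at -0.10 (percentile 1.00), ribosomal proteins at -0.08 (percentile 0.03) and oxidative phosphorylation at -0.08 (percentile 1.63). Under quantile and cyclic loess scaling the ribosomal median was -0.040 and -0.045 (percentiles 0.33 and 0.03) and that of oxidative phosphorylation -0.041 and -0.044 (percentiles 2.06 and 1.63). IER3 and NFKBIA were lower by 0.40 and 0.23 with sgTetO. The medians of the other 16 lists lay between -0.05 and 0.00, within the random range, and the p53 list's mean, 0.01, had the opposite sign to its median, -0.03.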

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

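Among probe sets outside the named genes, probe set 213710_s_at, with no gene listed here, was 1.05 log2 units or more higher on sgIL1RN1~3 than on both controls, at 7.88 against 6.82 with sgTetOmut and 6.49 with sgTetO. Of the 3207 probe sets outside the named genes, 1 lay 2-fold above and 1 lay 2-fold below both other arrays on sgIL1RN1~3, 0 did so on sgTetO in either direction, and 3 lay above on sgTetOmut.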

How the results depend on the processing

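No paired analysis was possible because each guide had 1 array, and for the same reason no replicate could be left out. Under quantile and cyclic loess scaling IL1RN moved by under 0.25 log2 units and each gene count by at most 1.5 times, the genes higher on sgIL1RN1~3 than on sgTetO falling from 6 to 4, and the 35 genes above both other arrays on sgTetOmut remained the same 35. The ribosomal protein median between the controls became -0.040 under quantile and -0.045 under cyclic loess scaling, outside its random lists in both. In all, 293 of the list medians under alternatives changed by no more than 0.5 of the width of the list's random range and 21 by more, none of those called reversing. A small change of the median or of the random range still altered the call on sgIL1RN1~3 for p53 targets under cyclic loess, hypoxia and glycolysis under both scalings and ribosomal proteins under quantile scaling. For p53 targets the median fell from 0.124 to 0.109, while the upper edge of the range fell further, from 0.127 to 0.107. Where a value changed, the cause was not tested, except that a limit or minimum level changes the number of genes by its construction. Low signal limits what can be seen: the IL1RN set that stands for the gene, and other genes at background, have only a bound on the controls.

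With the mean of all probe sets, IL1RN differed by 0.89 from sgTetOmut and 0.94 from sgTetO; with 16 added to the linear values, by 2.81 and 2.80. With no minimum level, 5 genes were above and 6 below both controls on sgIL1RN1~3, 14 were higher than on sgTetOmut, 14 higher and 13 lower than on sgTetO, and 2 were higher on sgTetO than on sgTetOmut. A minimum at the 25th percentile gave 5, 6, 14, 13, 13 and 1 genes in that order. A minimum at the 75th percentile, which IL1RN itself does not reach, gave 0 above and 0 below both controls on sgIL1RN1~3, 17 above on sgTetOmut, 0 higher and 18 lower on sgIL1RN1~3 than on sgTetOmut, 2 higher and 0 lower than on sgTetO, and 18 lower on sgTetO than on sgTetOmut. A limit of 1.5-fold gave 40 above and 35 below both others on sgIL1RN1~3, 1 and 1 on sgTetO, 1 below on sgTetOmut, 60 higher and 91 lower on sgIL1RN1~3 than on sgTetOmut, 116 and 84 against sgTetO, and 4 higher on sgTetO than on sgTetOmut. A limit of 3-fold gave 0 below both controls on sgIL1RN1~3, 20 above on sgTetOmut, 1 higher and 24 lower on sgIL1RN1~3 than on sgTetOmut, 1 and 0 against sgTetO, and 21 lower on sgTetO than on sgTetOmut. The mean of all probe sets gave 2 genes below both controls and 3 higher than on sgTetO for sgIL1RN1~3. Adding 16 gave 0 below both controls, 1 higher than on sgTetOmut and 1 lower than on sgTetO. As alternatives chosen after seeing the data, all probe sets gave 5 above and 13 below both controls on sgIL1RN1~3, 1 below on sgTetO, 53 above on sgTetOmut, 11 higher and 66 lower on sgIL1RN1~3 than on sgTetOmut, 26 and 29 against sgTetO, and 56 lower on sgTetO than on sgTetOmut, and sgTetO as the only control gave 6 higher and 4 lower on sgIL1RN1~3.

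Correlations with sgIL1RN1~3 were 0.993 (sgTetOmut) and 0.994 (sgTetO) at the 25th percentile and 0.978 and 0.982 at the 75th; that between the controls was 0.996 and 0.988. Adding 16 gave 0.997 for sgIL1RN1~3 with sgTetO and 0.998 between the controls. The interferon median on sgIL1RN1~3 was -1.91 against sgTetOmut alone and -0.16 against sgTetO alone, -1.25 at the 75th percentile and -0.89 with 16 added; between the controls it was -1.71 with the mean of all sets and -1.57 with 16 added. Against sgTetO alone the oxidative phosphorylation median was -0.020. At the 75th percentile, with 1 to 15 members left, medians on sgIL1RN1~3 were -0.26 for the IL-1 cluster, 0.0010 for hypoxia and glycolysis, 0.18 for histones, 0.61 for pluripotency genes, -0.13 for epithelia and 0.25 for neurons, and between the controls -0.12 for the unfolded protein response, -0.13 for epithelia and 0.072 for neurons. Between the controls, the 25th percentile gave -0.14 for histones and -0.22 for blood, and the mean of all sets -0.11 for cholesterol genes.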

Other observations

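The tests of explanations in this part were chosen after the result was seen, except the comparison of probe sets of one gene and the cyclic loess test, which were set before their values were known. The counts at any level and the interferon median against sgTetO alone were planned, and the bounds against background were not. Genes under the minimum level extended both patterns of the report. On sgTetOmut, 46 genes at any level read at least 2-fold above both other arrays, 25 of them on the interferon list. Against the highest Bacillus value, 44 of them and 24 of the list kept this distance, and APOL6 and XAF1 did not. The 11 additional genes included the chemokine genes CXCL10, by at least 2.72 log2 units over background, CCL5, by 1.47, and CXCL11, by at least 1.13 over background. They also included IFNB1, which encodes interferon beta, at 5.98 against 3.53 with sgTetO and 3.40 with sgIL1RN1~3, MX2, by at least 2.59, and GBP1, by 2.24. Against sgTetO alone, 22 of the 28 interferon genes were lower and 4 higher on sgIL1RN1~3, with a median of -0.16 (percentile 0.07 of random lists).

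On sgIL1RN1~3, 5 genes at any level were at least 2-fold above both controls and 6 below, named here because they are few. Those above were IL1RN, FGFBP1, an extracellular carrier of fibroblast growth factors, by 1.53 log2 units, AXL, a receptor tyrosine kinase, by at least 1.09 over background, ECM1, an extracellular matrix protein, by at least 1.33, and ZKSCAN1 by at least 1.03. The second sets of AXL and ZKSCAN1 were at background on all 3 arrays. Those below were SULT1C2 by 1.38, MICOS10P1 by 1.19, GPR22 by 1.12, CLEC2D by 1.06, KLF3 by 1.04 and ALOX5 by 1.02. Further ALOX5 sets were at background on all 3 arrays.

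The interferon genes on sgTetOmut were weighed against 3 technical explanations. The prediction set for scaling of the arrays was a shift of other genes at like levels. The 2390 level-matched genes outside the list had a median difference of 0.0090 log2 units. The list's median of 1.85 stayed at 1.83 under quantile and 1.85 under cyclic loess scaling. The deposited columns already had nearly the same distribution, so a small matched median and little change on rescaling would follow in any case. These values show that the list differed from genes of like level, and do not decide on the authors' scaling. Blood or endothelial cells in the sample predict their own markers, and 0 of 15 markers were 2-fold above both other arrays. An exchange of the control labels cannot be told apart, because no gene on the array identifies either control guide and IL1RN differed by 0.057 between them. IFNB1 was 2.46 log2 units above both other arrays, but it is itself on the interferon list, so this restates the pattern and is no separate test of an interferon response in this transfection. With 1 array per guide the guide sequence, the DNA preparation and the well stay open as its origin.

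The many small differences on sgIL1RN1~3 (75 genes 1.5-fold above or below both controls, against 2 on sgTetO and 45 on sgTetOmut, 44 of them above) were weighed likewise. A trend with level left in the deposited values is argued against, since 74 genes passed the same limit after cyclic loess scaling. Of these, 34 were above and 40 below both controls, against 40 above and 35 below as deposited. The columns had nearly the same distribution beforehand, so this scaling had little to remove. RNA integrity or the reach of labelling predicts a gain at 5' ends, and the 5' sets gained on the 3' sets by 0.82 log2 units for ACTB and 0.74 for GAPDH. Across 2016 genes with several sets, the dimmer set gained on the brighter one by a median of 0.044 on sgIL1RN1~3 over sgTetO (95% bootstrap interval over genes 0.031 to 0.061), against -0.013 (-0.022 to -0.0051) between the controls, which lay in the predicted direction but under the size set in advance. How much of the differences it accounts for, and whether the IL1RN guides add to them, cannot be told apart with 1 array.

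A further hypothesis was that activation might extend to the neighbours of IL1RN, taken as the 10 measured genes on each side in the GRCh38.p14 gene order. The 14 of them above background on at least 1 array had a median difference from the mean of both controls of -0.026 log2 units (percentile 22.6 of random lists), and 0 were 2-fold above both. They ranged from -0.37 for SLC35F5 to 0.54 for STEAP3. The other 6, IL1B, IL37, IL36G, IL36A, IL36RN and PSD4, are the 5 nearest measured genes on one side of IL1RN and the nearest on the other, and reached at most 3.18 on sgIL1RN1~3, under the highest Bacillus value, so a small rise of these genes would stay unseen. The values argue against a 2-fold spread to the measurable neighbours, most of them further away, and leave these 6 open.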
